A study of Mus musculus with 2 samples.

How the data were processed

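Dorsal skin RNA of Mpzl3 null and wild-type littermates was measured on Agilent Whole Mouse Genome arrays with 2 dyes, per the labels. RNA was extracted with TRIzol, purified on RNeasy columns, amplified to amino allyl RNA and coupled with Cy3 or Cy5, per the labels' protocols. There were 2 arrays, 1 for pups aged 1 day and 1 for pups aged 9 days. Null RNA was in Cy5 and wild-type RNA in Cy3 on both, per the labels, and dye and genotype can therefore not be separated. Both arrays lay on 1 slide by their titles. Whether each channel held 1 pup or a pool is not given in the sources used here.

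The values are the log2 ratios that the authors deposited in 1 table with 39212 rows and 1 column per array. Background correction, dye normalization and the filter that left cells blank are not given in the sources used here. The base of the logarithm was inferred from the values. The largest size in the table, 4.898, is 29.8-fold in base 2 and would be 79067.9-fold in base 10. A natural logarithm was not compared, so fold values rest on this inference. Direction was taken from the dyes in the labels alone; the value of Mpzl3 and the correlation of the arrays do not check it. The median of all values was −0.007 at P1 and 0.005 at P9, so the columns appear centred, but how they were centred stays unknown. Blank cells made up 11.3% of the P1 column (4436) and 4.71% of the P9 column (1846). The blanks fell on different genes. Of 97 ribosomal protein probes, 2 were blank at P1 and 44 at P9, and of 910 olfactory and vomeronasal receptor probes, 381 were blank at P1 and 66 at P9. No spot intensity was used here, so dim and bright spots could not be told apart and no filter on signal was applied. There were 0 columns of unmapped samples.

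Probes were named from the platform annotation. Of the rows, 31337 named 1 gene, 40 named several and were left out, 7744 had no name here, and 91 were control spots, which were left out of gene results. Symbols were checked through Entrez identifiers against the RefSeq gene table of GRCm38.p6, which matched 31210 probes and left 127 with the annotation's own symbol. This gave 18855 genes, of which 8153 had at least 2 probes. The list of genes that neighbour Mpzl3 was written by name, and no coordinate was used. The arrays name older symbols for some genes, such as Il1f6, Il1f9 and Il1f5 for members of the interleukin-36 family.

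A gene's value was the mean of its probes. The SD between probes was pooled over genes with at least 2 probes (7442 genes and 18586 probes at P1, 7735 genes and 19480 probes at P9). It describes probes and spots within 1 array and says nothing of variation between animals. With 1 array per age no test across genes was run. A gene passed where its mean log2 ratio was at least 1 in size, a 2-fold ratio, and all its probes had the same sign.

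Before the data were examined, 36 gene lists were fixed for epidermal, hair, gland, lipid, cell type, immune and housekeeping functions, together with the rule for named genes. Each list was summarised by its median, the bootstrap SD over members (1000 resamples) and the percentile of the median among 10000 random lists drawn with replacement from measured genes, matched on the number of probes per gene (1, 2, or at least 3). Matching on expression level was not done, for lack of intensities. A percentile describes these arrays and is not a p-value, since genes of a list are not independent. The lists of receptors, numbered zinc finger genes and X-linked genes that escape inactivation were added after the data were seen.

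The rule named Mpzl3, the 10 highest and 10 lowest genes at each age, the 4 members with the largest size from each called list, any member past 2-fold that leads another list, the 8 leading genes shared in each direction, the 6 leading genes with opposite directions each way and the sex-linked genes. Clone and prediction names were left out of the extremes. The text gives a selection of these, and the few genes outside the rule are marked where they appear.

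Alternatives changed the fold threshold, the summary over probes, the probes and genes used, the centring and scaling of the arrays, and the summary, members and random pool of the lists. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data with the probe layout and spread of the arrays and 200 changed genes, of which 182 had a value in the P1 layout and 192 in the P9 layout. Changes of 1.5 log2 were recovered for 90.0% of 60 genes in the P1 layout and 88.9% of 63 genes in the P9 layout, and changes of 2 and 3 log2 for 100% in both. Of unchanged genes, 0.311% passed 2-fold in the P1 layout and 0.376% in the P9 layout. These genes were given probe spread only, with no shift common to a gene or family and no variation between animals. The rates are therefore not false-call rates of the real arrays. In the P9 layout, 12 of a first 100 unshifted lists of 20 genes fell in the highest or lowest 2.5%, more than the nominal rate, and a larger draw of 2000 lists, added for that reason, gave 4.40%. All 100 lists shifted by 0.5 log2 lay in the highest 2.5%.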

Results

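Gene expression in the dorsal skin of newborn and young mice was compared between Mpzl3 null pups and their wild-type littermates. Mpzl3 encodes a transmembrane protein with an immunoglobulin-like domain, and the series title links its loss to a skin phenotype resembling seborrheic dermatitis. The data consisted of 2 arrays with 2 dyes each, 1 array for pups aged 1 day (P1) and 1 array for pups aged 9 days (P9). RNA labelled null carried Cy5 and wild-type RNA carried Cy3 on both arrays, so the dyes were not swapped. Each value is a log2 ratio of null over wild type, and positive values mean a higher signal in the channel labelled null. The P1 array gave a value for 17233 genes and the P9 array for 18269 genes. With 1 array per age there is no replicate check, and no p-value is given; the number of arrays limits the precision. The SD between probes of 1 gene was 0.36 log2 at each age, a spread of 1.28-fold, which covers probes and spots but not animals. A gene is called higher or lower where its mean ratio was at least 2-fold and its probes all had 1 sign. A gene list is called high or low where its median lay in the highest or the lowest 2.5% of 10000 random gene lists of its size; the ± after a list median is its bootstrap SD over members.

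The targeted gene was examined first. Mpzl3 was measured by 1 probe, with a log2 ratio of −0.21 at P1 and 0.20 at P9, both smaller than the spread between probes. Where this probe lies relative to the deleted part of the gene is not given in the sources used here, so its value does not check the genotype labels, and "null" means the channel labelled null throughout. The genes that neighbour Mpzl3 had a median of 0.13 ± 0.14 at P1 over 24 genes and 0.02 ± 0.09 at P9 over 25 genes, and 0 of them passed 2-fold at either age. Without members that another list holds, the P1 median was 0.33 and was called high.

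The P1 array asked how null skin differed within 1 day of birth. The small proline-rich proteins and genes of the hair shaft had high medians, and genes of the interferon response had a low one. Other lists of the cornified layer were not called at P1, with medians of 0.02 ± 0.05 for the late cornified envelope family and 0.11 ± 0.11 for late differentiation, and 0 of their genes passed 2-fold. Of the sex-linked genes, only 2 of 4 had a value at P1, and neither passed the rule. The Y-linked genes Eif2s3y and Kdm5d were blank, and Uty had a value at 2 of its 4 probes. Xist, which is expressed from the inactive X chromosome, was at −1.03 ± 0.77 (SD, 4 probes), with 3 probes from −1.41 to −1.42 and the other at 0.12, and the Y-linked gene Uty was at 0.33 ± 0.57 (SD, 2 probes). The small proline-rich proteins, which are cross-linked into the cornified envelope, had a median of 0.70 ± 0.20, and 4 of the 13 measured members passed 2-fold. Sprr3 was the highest of them at 2.03, followed by Sprr2g at 1.27, Sprr2k at 1.14 and Sprr2j-ps, listed as a pseudogene by its symbol, at 1.07. The keratin-associated proteins, which embed the keratin filaments of hair, had a median of 0.89 ± 0.06, with 14 of 40 past 2-fold, among them Krtap16-3 at 1.43 and Krtap5-4 at 1.29. Hair shaft keratins had a median of 0.52 ± 0.06 over 11 genes, of which 1, Krt34, passed 2-fold at 2.79-fold. The sequences within these families are alike, and a probe may take up signal from a related gene, so single family members are uncertain.

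Genes of the epidermal barrier had smaller shifts at P1. Barrier lipid processing had a median of 0.32 ± 0.19 with 10 of 17 genes above 0. Its mean of 0.19 was not called, and its median over members with at least 2 probes was −0.0016. The list was led by Alox12b at 0.93 ± 0.32 (SD, 2 probes) and Slc27a4 at 0.72, a lipoxygenase and a fatty acid transporter of the epidermal barrier. Skin proteases and their inhibitors had a median of 0.36 ± 0.12 over 18 genes, but −0.17 over members with at least 2 probes, and their mean of 0.16 was not called. Klk10 was at 0.84, whereas Tmprss11f, a transmembrane serine protease, was lower at −1.28. Markers of tissues beside the epidermis also differed between the channels at P1. Skeletal muscle genes had a median of 0.78 ± 0.11, with 5 of 25 past 2-fold, including Myh2 at 1.55, Actn3 at 1.34 and Myh7 at 1.32. White adipocyte genes had a median of 0.36 ± 0.11 over 19 genes, with Plin4 at 0.85 and Lipe at 0.82, and 0 of them passed 2-fold. Schwann cell genes had a median of 0.47 ± 0.13 over 7 genes, led by the myelin gene Mag at 0.95.

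Lists with a low median at P1 were those of innate defence and translation. Interferon response genes had a median of −0.33 ± 0.10, and 3 of 23 were past 2-fold, Ifit1 at −1.86, Iigp1 at −1.36 and Gbp3 at −1.33. Chemokines and cytokines had a median of −0.22 ± 0.08, with 22 of 30 below 0 and 0 past 2-fold. Il6 was at −0.77 and Ccl3 at −0.81. Genes of barrier stress and alarmins, which keratinocytes and leukocytes make when the barrier is injured, had a median of −0.22 ± 0.17 with 17 of 24 below 0. Of these only Stfa2 passed 2-fold, at −1.19, while Saa1 was at 0.85. Ribosomal protein genes had a median of −0.14 ± 0.06 over 60 genes. Single members of lists that were not called passed 2-fold too. Dcn, which encodes decorin, was at −1.56, Col1a2 at −1.12, the desmosomal gene Dsg1a at −1.03, the mast cell receptor Mrgprb2 at −1.18 and Cd4 at 1.37.

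In all, 296 genes were higher and 201 lower past 2-fold at P1, or 177 and 103 with both arrays centred and scaled to 1 spread. Olfactory and vomeronasal receptors, sensory genes of the nose, made up 85 of the 296, or 28.7%, against 2.99% of the genes measured. They include Olfr749 at 2.07 and Olfr744 at 1.98, and the receptor family as a whole had a median of 0.34. Numbered zinc finger genes made up 41 of the 201 lower genes, or 20.4%, against 1.93% of the genes measured, and the family had a median of −0.29, with Zfp994 at −2.02, Zfp936 at −1.96 and Zfp946 at −1.91. Also among the 10 highest and 10 lowest genes were Meiob at 1.98 and Hmx3 at 1.95, and Pof1b at −2.09, Rps6ka6 at −1.76 and Tvp23b at −1.75. Pof1b encodes an actin-binding protein of epithelial junctions. Of the genes past 2-fold, 281 of the 296 higher and 128 of the 201 lower rested on 1 probe with a value on this array. Over members with at least 2 probes, the medians of white adipocyte (0.25), chemokine (−0.20), interferon (−0.31) and ribosomal genes (−0.18) were no longer called but kept their sign.

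The P9 array asked the same question at 9 days of age. The channels of this array differed in sex-linked transcripts. Xist was 12.7-fold higher in the null channel, at 3.67 ± 1.05 (SD, 4 probes). The Y-linked genes Eif2s3y and Kdm5d were at −3.98 and −1.76, and Uty was at −1.99 ± 1.46 (SD, 4 probes, 1 of them at exactly 0). All P9 values below were therefore measured between channels that differ in these transcripts as well as in the genotype label.

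Genes of barrier stress and alarmins were high at P9, with a median of 0.39 ± 0.16, or 0.10 and not called over members with at least 2 probes. Of the 24 genes, 21 lay above 0. Past 2-fold were 6 of them. S100a9, a subunit of calprotectin, was 4.12-fold higher at 2.04. The other subunit, S100a8, named here after its value was seen, was within 2-fold at 0.33, and each rests on 1 probe. The antimicrobial genes Defb14, Defb3 and Lcn2 were past 2-fold at 1.27, 1.13 and 1.10. The remaining pair, Krt16 at 1.08 and Il1b at 1.04, is named here after its values were seen. Ccl20, a chemoattractant of dendritic cells and T cells, was at 1.81, although the list of chemokines and cytokines was not called at P9, with a median of 0.14 ± 0.10. Immediate early and stress genes had a median of 0.36 ± 0.09, with 4 of 19 past 2-fold. These were Fosb at 1.61, Nr4a1 at 1.36, Atf3 at 1.23 and Fos at 1.06 ± 1.04 (SD, 2 probes).

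**Figure D1:**
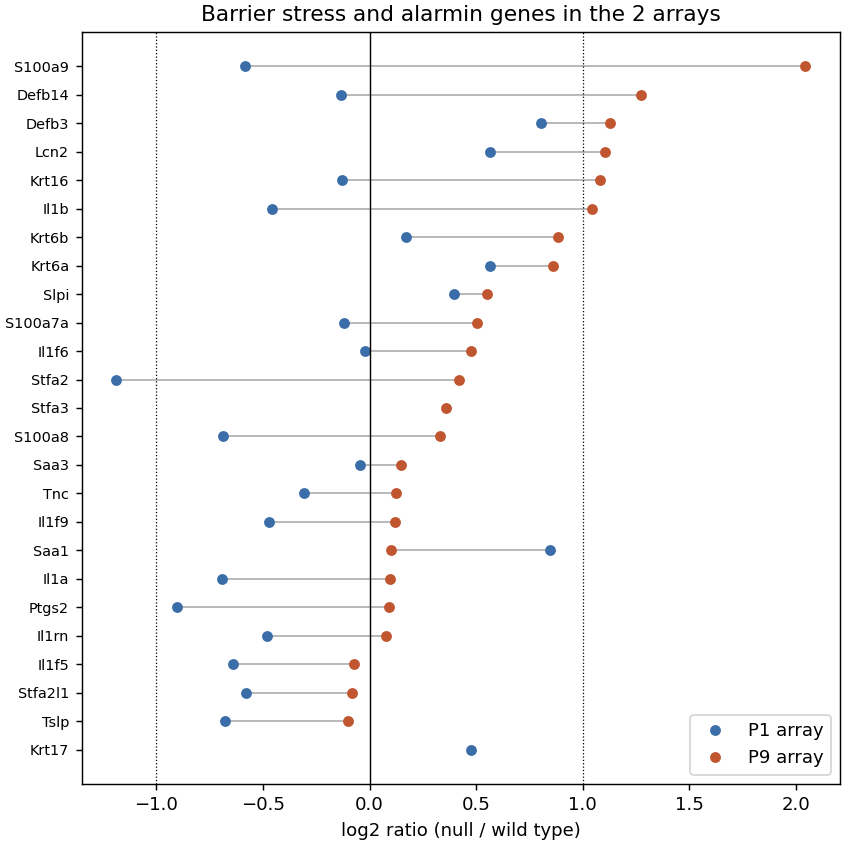
Log2 ratios (null over wild type, horizontal axis) of the genes in the list of barrier stress and alarmins, 1 row per gene, at P1 (blue) and P9 (orange). Dotted lines mark 2-fold and a gene with 1 point was blank on the other array; the median was −0.22 at P1 and 0.39 at P9, and S100a9 moved from −0.58 to 2.04.

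Epidermal differentiation genes were high at P9 as well. The late cornified envelope family had a median of 0.52 ± 0.08, with 13 of 14 above 0 and 0 past 2-fold, and the leading members were Lce1l at 0.93 and Lce3c at 0.87. Other late differentiation genes had a median of 0.42 ± 0.06, with 18 of 20 above 0. Flg, which encodes filaggrin, was at 0.96, Dmkn at 0.73, Cnfn at 0.56 and Casp14 at 0.55. The small proline-rich proteins had a median of 0.89 ± 0.18, and 6 of 12 passed 2-fold, led by Sprr2d at 2.14 and Sprr2g at 1.44. Interfollicular keratins had a median of 0.47 ± 0.13 over 5 measured genes, with Krt10 at 0.64 and Krt1 at 0.50. The basal keratins Krt5 and Krt14 were blank on this array. Keratin-associated proteins had a median of 0.66 ± 0.14, with 8 of 27 past 2-fold, including Krtap4-16, 2.80-fold higher, and Krtap4-13, 2.73-fold higher. Hair shaft keratins were not called at P9, with a median of 0.25 ± 0.27, and Krt34 was at 1.01. Only 7 of the 11 genes measured at P1 had a value here. Over these, the difference of P9 minus P1 was −0.22, at the 11.4 percentile of random lists.

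Lipid and gland genes were shifted by smaller amounts. Sebaceous gland genes had a median of 0.31 ± 0.15 over 12 genes, with Krt79 at 0.82, Elovl3 at 0.80 and Scd1 at 0.67, and 0 passed 2-fold. Over the members with at least 2 probes, which were only Far2, Mgst1 and Dgat2, the median was −0.06. Barrier lipid processing had a median of 0.34 ± 0.10, with 15 of 17 above 0, led by Degs2 at 0.99 and Alox12b at 0.86. Fatty acid synthesis had a median of 0.24 ± 0.06, and of its 16 genes only Fads2, the delta-6 desaturase, passed 2-fold at 1.18, while Scd2 was at −0.82. Brown adipocyte genes had a median of 0.35 ± 0.18 over 11 genes. Ucp1, the uncoupling protein of brown fat, was 2.96-fold higher at 1.57. Skin proteases and inhibitors had a median of 0.32 ± 0.16 over 18 genes, of which only Klk6 passed 2-fold, at 1.17. Among leukocyte lists, macrophage and dendritic cell genes had a median of 0.20 ± 0.05 and neutrophil genes of 0.29 ± 0.15. In the latter Cxcr2 was at 0.63 and Chil3 at 0.60, and Camp was lower at −1.06. Skeletal muscle genes had a median of 0.25 ± 0.05, with 23 of 25 above 0 and 0 past 2-fold.

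The dermal matrix and melanocyte lists had low medians at P9, with 1 gene of each past 2-fold. Dermal fibroblast and matrix genes had a median of −0.13 ± 0.06 over 21 genes, with Col1a2 past 2-fold at −1.20, Lox at −0.98 and Lum at −0.75, but Eln at 0.61; at P1 Col1a2 was at −1.12, Lum at −0.66 and Eln at 0.68. Melanocyte genes had a median of −0.41 ± 0.28 over 9 genes, with Oca2 past 2-fold at −1.24, Slc24a5 at −0.77 and Tyrp1 at −0.73, and Slc45a2 at 0.81. Outside these lists, Mup5, a major urinary protein gene, was at −2.28, Pcdh8 at −1.76, Cep20 at −1.69, Aspn, which encodes asporin of the extracellular matrix, at −1.62, Axin2, a target and inhibitor of Wnt signalling, at −1.56 and Esco2 at −1.46. The mast cell gene Ms4a2, in a list that was not called, was at 1.00 (1.005 before rounding).

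In all, 409 genes were higher and 85 lower past 2-fold at P9, or 596 and 186 with both arrays centred and scaled to 1 spread, so that which age had more lower genes depended on the scaling. Olfactory and vomeronasal receptors made up 127 of the 409, or 31.1%, against 4.47% of the genes measured, and had a median of 0.19. They include Olfr1408 at 1.92, Olfr518 at 1.89 and Olfr218 at 1.85. Numbered zinc finger genes made up 10 of the 85 lower genes and had a median of −0.20. Mobp, at 1.72, was among the 10 highest genes. Of the genes past 2-fold, 386 of the 409 higher and 75 of the 85 lower rested on 1 probe with a value on this array. Over members with at least 2 probes, the alarmin median was 0.10 and was not called, and the late cornified envelope (0.34), brown adipocyte (0.19), macrophage (0.23), protease (0.12) and dermal matrix (−0.079) medians were not called but kept their sign. By their means, interfollicular keratins, fatty acid synthesis, macrophage and neutrophil genes (0.12) were not called, and the brown adipocyte call ended without members shared with other lists and the dermal matrix call against random lists without receptors.

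**Figure D2:**
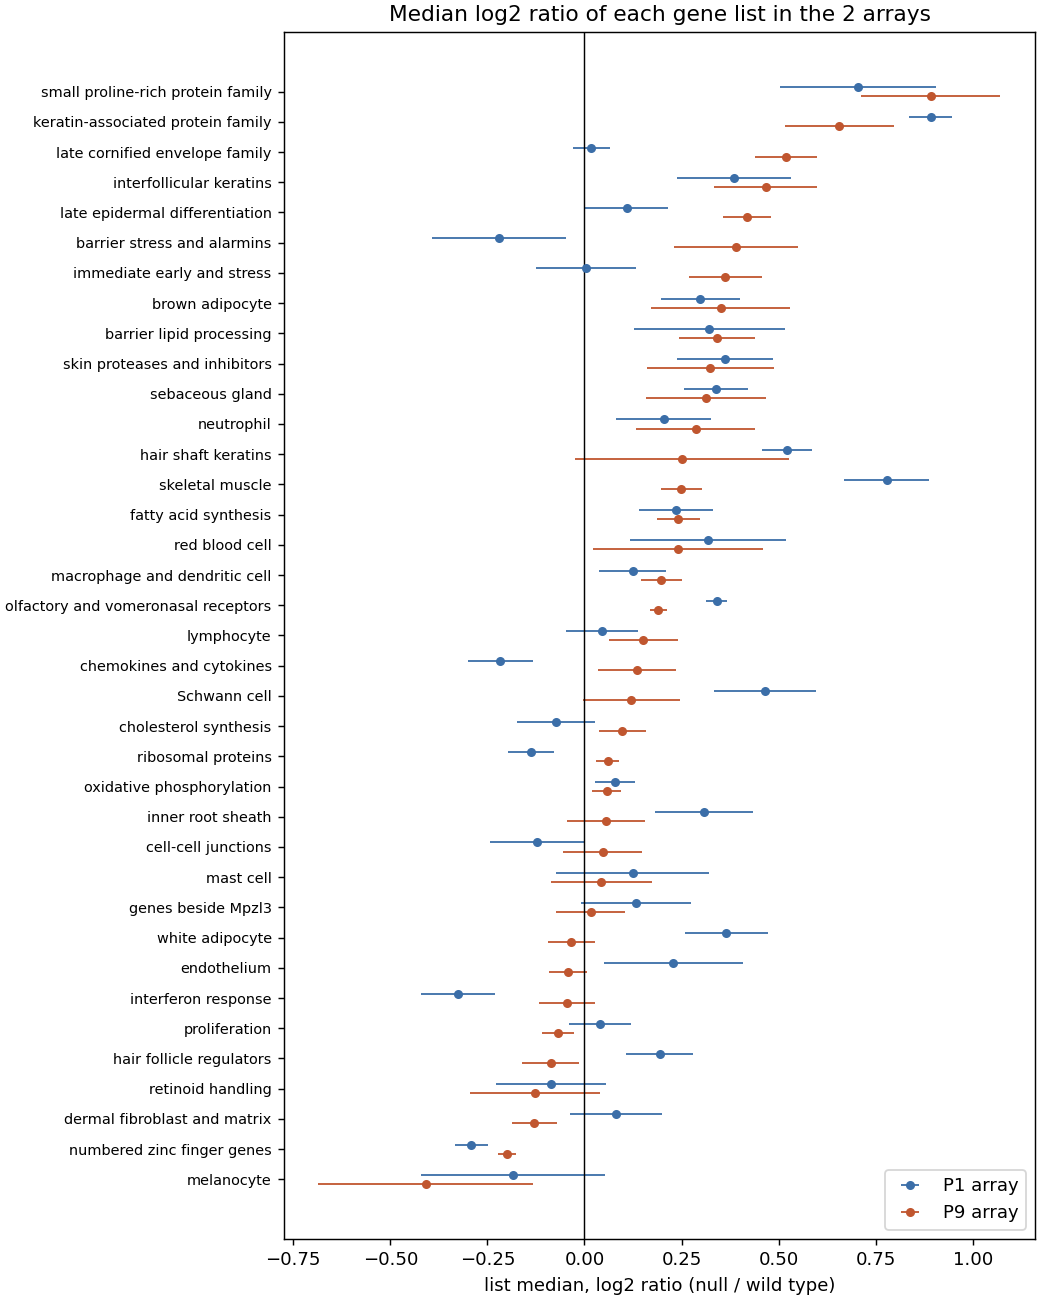
Median log2 ratio (null over wild type, horizontal axis) of each gene list at P1 (blue) and P9 (orange), with bars of 1 bootstrap SD over members. The sex-linked and X-linked lists are left out; the small proline-rich proteins lay at 0.70 and 0.89, and the alarmins at −0.22 and 0.39.

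Comparing the ages asked which differences were shared by P1 and P9 skin and which were not. Across the 16647 genes measured on both arrays, which are not independent replicates, the log2 ratios correlated with Pearson's r = 0.674, and 74.3% of the genes had the same sign. Past 2-fold at both ages were 143 higher genes, where independent lists would share 6.22, and 44 lower genes, where independent lists would share 0.992. The number past 2-fold in opposite directions was 0. Without receptors and numbered zinc finger genes, an alternative chosen after seeing the data, 84 higher and 37 lower genes were shared. Shared higher genes outside the receptors included Ftcd at 1.62 and 1.52 (P1, then P9), Bpifa5 at 1.54 and 1.38 and Tmc8 at 1.38 and 1.56. Shared lower genes included Aspn at −1.69 and −1.62, Pof1b at −2.09 and −1.46, Sft2d1 at −1.61 and −1.43 and Smad7, an inhibitor of TGF-β signalling, at −1.34 and −1.32. The correlation was also present over 79 control spots, with r = 0.560. Control spots were told by their names alone, and what each measures was not examined. Differences of each probe from the mean of its gene correlated between the arrays with r = 0.673, and 1 probe at P1 correlated with another probe of the same gene at P9 with r = 0.246.

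**Figure D3:**
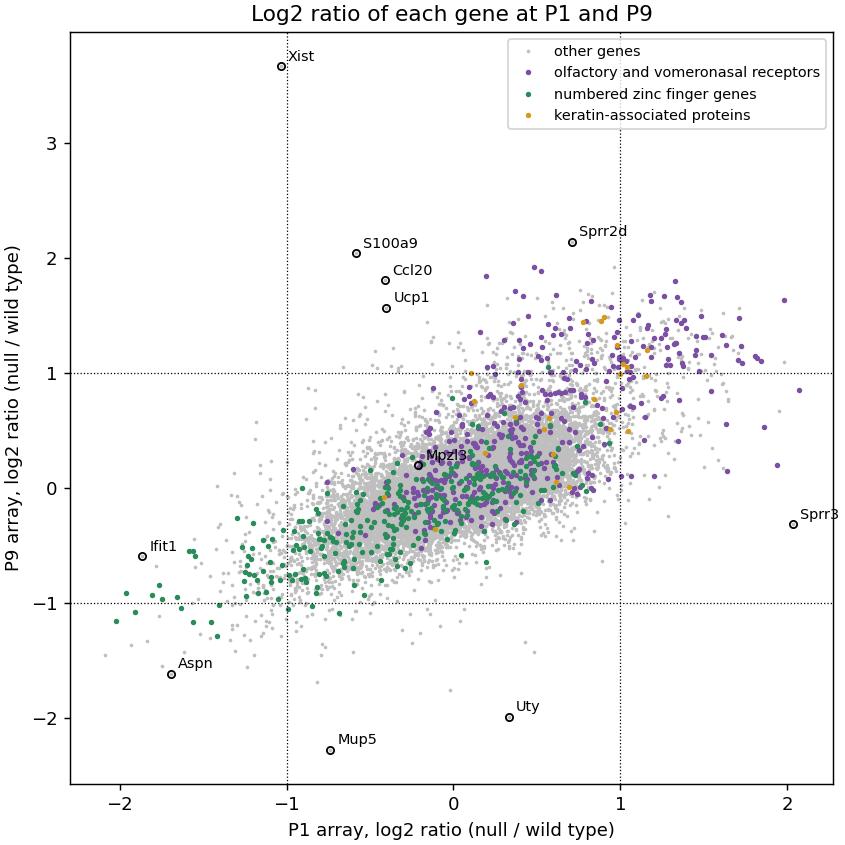
Log2 ratio (null over wild type) of each gene at P1 (horizontal axis) and P9 (vertical axis), 1 point per gene measured on both arrays, with the coloured families named in the legend and dotted lines at 2-fold. The ratios correlate (r = 0.674); Xist at 3.67, S100a9 at 2.04 and Ccl20 at 1.81 on the vertical axis lie away from the main cloud.

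The difference of P9 minus P1, taken gene by gene from the means of the probes with a value at each age, separated several lists. This difference was 0.57 ± 0.08 for alarmins, with 22 of 23 genes above 0, and 0.58 ± 0.09 for the late cornified envelope family, with 12 of 12 above 0. It was 0.26 ± 0.14 for late differentiation, 0.29 ± 0.09 for immediate early genes, 0.25 ± 0.08 for the interferon response and 0.23 ± 0.11 for chemokines and cytokines. Skeletal muscle genes had a difference of −0.46 ± 0.09 with 22 of 25 below 0, white adipocyte genes of −0.32 ± 0.08 with 16 of 19 below 0, and endothelial genes of −0.28 ± 0.09 with 11 of 11 below 0. Keratin-associated proteins, high at both ages, had a difference of 0.04 ± 0.08 over the 25 of 42 genes measured on both arrays. Genes high at P1, such as Krtap16-3 at 1.43 and Krtap5-4 at 1.29, were blank at P9 and are not part of it. Single genes below 0 at P1 and above 0 at P9 included the serine protease inhibitors Serpinb3a, from −0.66 to 1.05, and Serpinb3c, from −0.83 to 0.85, Sirpb1b from −0.87 to 0.87, Casp4 from −0.88 to 0.60 and Ccl8 from −0.65 to 0.61. In the other direction Serpina3b went from 0.48 to −1.43, Cyp2f2 from 0.43 to −1.34 and Slc16a3, a lactate transporter, from 0.89 to −0.64. The sex-linked transcripts also differed between the arrays, and no test of these differences against animals was possible with 1 array per age.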

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

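The tests of the receptor genes, of the P9 minus P1 difference of the alarmins and of the dye effect on Xist were chosen after the values they use were seen. Both results below went one way at P1 and the other way at P9; with 1 array per age, neither difference was tested.

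The first is the list of barrier stress and alarmins, with a median of −0.22 at P1 and 0.39 at P9. Over members with at least 2 probes, the median was −0.48 at P1, still called, and 0.10 at P9, not called. A bias of the same size on both arrays is argued against as the whole cause, since it would also have raised the list at P1; the difference of P9 minus P1 had a median of 0.57 (bootstrap SD 0.08), which restates the values that drew attention to the list and excludes no bias that differs between the arrays. More neutrophils in the P9 null skin stay open: the neutrophil median lay at the 98.2 percentile, which met the criterion set beforehand, but the mean of the list lay only at the 68.9 percentile, Camp was at −1.06 and the P9 minus P1 median was −0.20. The requirement that the mean also pass was added after the result was seen, because these values conflict. Sex cannot be told apart from the genotype label, as Xist was at 3.67 on the same array, and a response of null skin that appears after P1 remains among the open explanations, as does variation between pups.

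The second is Xist, at −1.03 at P1 and 3.67 at P9, with Y-linked genes low at P9; a dye effect of the same size on both arrays is argued against, because Xist differed by 4.70 between them. Channels of different sex composition at P9 have the values they need. All 4 Xist probes lay from 2.26 to 4.81, Eif2s3y was at −3.98 and Kdm5d at −1.76. Uty was at −1.99, with 1 of its 4 probes at exactly 0. Null and wild-type pups of opposite sex, with a female null sample, are a candidate source of that difference. Of 4 X-linked genes that escape inactivation, the median at P9 was 0.23, between the bounds set for and against opposite sex. This median therefore does not decide. Kdm5c was at 0.54, Kdm6a at 0.42, Ddx3x at 0.04 and Eif2s3x at −0.13 ± 0.88 (SD, 4 probes). The difference of P9 minus P1 of these genes, taken after the values were seen, had a median of 0.41. It had 4 of 4 genes above 0 and lay at the 99.3 percentile of random lists. This difference also holds the P1 ratios, with a median of −0.39, so it does not decide for P9 alone. The labels used here give no sex, and a pool of unequal sex composition stays open. At P1 neither Xist nor Uty (0.33, SD 0.57) passed the rule, and Eif2s3y and Kdm5d were blank. Xist failed the rule through 1 probe at 0.12, and its other probes lay from −1.41 to −1.42. The escape genes went both ways there, with Ddx3x at −0.57, Kdm6a at −0.43, Eif2s3x at −0.34 and Kdm5c at 0.50. Whether sex differed at P1 was not tested, so the P1 values are not shown to be free of a sex difference.

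A pattern behind many of the calls is the correlation of the P1 and P9 ratios. A dye effect that belongs to single probes has the values it needs: deviations of probes from their gene's mean correlated with r = 0.673, and control spots with r = 0.560, or 0.437 by ranks, over 79 spots. Any difference between a gene's probes that recurs on both arrays would also give the value of 0.673, which therefore does not single out dye. What the control spots measure was not examined, so their value does not single out dye either. Receptor genes lay above other genes by 0.17 at P9 and 0.29 at P1, which cannot bear on a bias of dim spots, since they were picked for being high. For a gene-level effect shared by both ages, 1 probe at P1 and another probe of its gene at P9 correlated with r = 0.246. The 95% interval, 0.224 to 0.268, is over 7049 genes, which are not independent replicates, and covers no variation between arrays or animals. The value lay between the bounds set for and against such an effect. Different probes correlated with 0.235 within the P9 array and 0.442 within the P1 array. An effect confined to single probes would not link different probes of a gene, so part of the correlation was shared by a gene's probes. Its cause stays open. A genotype effect or a dye effect that follows a gene's sequence or signal could give the value of 0.246. Without a dye swap the genotype and the dye cannot be told apart for genes that differ alike at both ages.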

How the results depend on the processing

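The alternatives without receptors and numbered zinc finger genes, with random lists drawn without receptors, and over probes with a value on both arrays were chosen after seeing the data. Of the alternatives for counts, 47 stayed within 1.5 times the main count and 23 did not. At 1.5-fold, 1564 genes were higher and 1193 lower at P1, 1128 higher and 603 lower at P9, 538 and 374 shared, and 8 opposite. At 3-fold the counts were 37 and 17 at P1, 36 and 6 at P9, and 1 and 1 shared. These follow from the threshold. Among the fewer genes with at least 2 probes on both arrays, 13 were higher and 72 lower at P1, 19 and 9 at P9, and 4 and 8 shared. With the arrays centred and scaled to 1 spread, 177 were higher and 103 lower at P1, and 596 higher and 186 lower at P9. Without receptors and numbered zinc finger genes, 84 higher genes were shared.

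The correlation of the ages was 0.656 by ranks, 0.685 over all probes, 0.778 over genes past 2-fold at either age, 0.711 over genes with at least 2 probes on both arrays and 0.656 without receptors and numbered zinc finger genes. Over probes with a value on both arrays, the P9 minus P1 medians of 14 lists that stood outside the random range kept their direction and stayed outside it, with 0.59 for alarmins and −0.46 for skeletal muscle.

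For called lists, 182 alternatives kept call and direction, 18 lost the call and 3 reversed. The 182 overstate stability: centring moves random lists too, and dropping shared members altered few medians. Over members with at least 2 probes, the median reversed for sebaceous gland at P9 (−0.057), barrier lipid processing at P1 (−0.0016) and skin proteases at P1 (−0.17). With the same members, the call ended at P9 for late cornified envelope (0.34), alarmins (0.10), brown adipocyte (0.19), macrophage and dendritic cell (0.23), proteases (0.12) and dermal matrix (−0.079), and at P1 for white adipocyte (0.25), chemokines (−0.20), interferon response (−0.31) and ribosomal proteins (−0.18). By the mean over members, it ended at P9 for interfollicular keratins (0.39), fatty acid synthesis (0.19), macrophage and dendritic cell (0.13) and neutrophil (0.12), and at P1 for barrier lipid processing (0.19) and proteases (0.16). Without members that another list holds, brown adipocyte at P9 (0.27) lost its call, and against random lists without receptors, dermal matrix at P9 (−0.13) did. Lists that were not called gained a call in 6 cases: sebaceous gland at P1 against unmatched random lists and random lists without receptors (0.34 in both) and without shared members (0.40), red blood cell at P9 by the mean (0.42), lymphocyte at P9 over members with at least 2 probes (0.30) and the neighbours of Mpzl3 at P1 without shared members (0.33). The cause was not tested, and fewer members also widen the random range. Too few members had at least 2 probes to give a value for hair shaft keratins at P1, interfollicular keratins, keratin-associated proteins, melanocyte and sex-linked genes at P9, and small proline-rich proteins at either age.

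Of single named genes and the spread, 1006 values kept their side of 2-fold or their size, 17 passed it and 10 fell short of it, and the P9 spread by the median absolute deviation was 0.30 against 0.36. Another log base, a turned sign and the removal of a repeated cap were not run. The base was inferred from the largest value, and no extreme value repeats. A turned sign was planned only for arrays that correlate below 0, and a positive correlation does not check direction. Each ratio already sets null against wild-type skin on 1 array; a fit of an effect common to both ages, with 1 residual degree of freedom, was not run. With 1 array per age there is no replicate to leave out. How far signals lay above background is not known here, and this limits all values from dim spots.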

Other observations

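Several cell types and pathways, some of them also named above, showed small shifts that were not called at either age as set beforehand. A few were called under an alternative, as given with the processing. Hair follicle regulators had a median of 0.19 at P1 and −0.09 at P9, and inner root sheath genes 0.31 and 0.06. Red blood cell genes were at 0.32 and 0.24, lymphocyte genes at 0.05 and 0.15, mast cell genes at 0.12 and 0.04 and endothelial genes at 0.23 and −0.04. Cholesterol synthesis, from which barrier sterols derive, was at −0.07 and 0.10, retinoid handling at −0.09 and −0.13, and oxidative phosphorylation at 0.08 and 0.06, with 0 of 69 and 0 of 70 genes past 2-fold. Proliferation genes were at 0.04 and −0.07, with 0 of 25 past 2-fold at each age. Cell-cell junction genes were at −0.12 and 0.05, but their difference of P9 minus P1, 0.17 ± 0.07, lay at the 98.9 percentile of random lists. Melanocyte genes, low at P9, were at −0.18 at P1. Lists called at P9 and not at P1 had P1 medians of 0.0045 for immediate early and stress genes, 0.02 for the late cornified envelope, 0.11 for late differentiation, 0.39 for interfollicular keratins, 0.34 for sebaceous gland, 0.24 for fatty acid synthesis, 0.30 for brown adipocytes, 0.12 for macrophages and dendritic cells, 0.20 for neutrophils and 0.08 for dermal matrix. A call at 1 age only does not show that the ages differed. P9 minus P1 lay within the random range for interfollicular keratins (−0.07), sebaceous gland (0.04), fatty acid synthesis (−0.03) and macrophages and dendritic cells (0.07). The same held for neutrophils (−0.20), dermal matrix (−0.09) and melanocytes (−0.04). It lay outside that range for immediate early genes, the late cornified envelope, late differentiation and brown adipocytes. Among lists called at P1 and not at P9, the P9 medians were −0.05 for the interferon response, 0.12 for Schwann cells and 0.06 for ribosomal proteins. Of these, P9 minus P1 lay within the random range for Schwann cells (−0.24) and outside it for the interferon response and ribosomal proteins.

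White adipocyte genes had a median of 0.36 at P1 and −0.03 at P9. Brown adipocyte genes went both ways: Ucp1 went from −0.40 to 1.57 and Cidea from 0.40 to 0.73, whereas the difference of P9 minus P1 was −0.45 for Dio2 and −0.42 for Cpt1b, chosen after their values were seen. The brown list's difference was 0.19 ± 0.20, with 6 of 10 genes above 0, and the lists were not tested against each other. Elovl3, at 0.28 and 0.80, is held by both the brown adipocyte and the sebaceous gland lists. The range of tissue taken with the dorsal skin is not given in the sources used here, and the P9 channels also differed in Xist.

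The small proline-rich family was not uniform. Sprr3 went from 2.03 at P1 to −0.32 at P9, while Sprr2d went from 0.71 to 2.14 and Sprr2b, chosen after its values were seen, from 0.70 to 1.03. Each of these rests on 1 probe.

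The lowest value of each array, −4.898 at P1 and −4.258 at P9, and the highest P1 value, 2.159, belonged to probes without a gene name here. The highest P9 value, 4.806, was an Xist probe.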
